A study of Mus musculus with 4 samples.

How the data were processed

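Regulatory T cells were sorted as DAPI-negative CD4+ TCRβ+ cells from the upper 50% of CD25-high staining, and 50000 cells per library were lysed and transposed, per the labels' protocols. The labels mention a double sort and the series design a single one. The libraries were sequenced paired-end with a 75-bp kit on a NextSeq instrument, per the labels' protocols. The submitters' processing notes name Bowtie2, Picard 1.130, SAMtools, HOMER 4.6, DiffBind and the mm9 genome build, without saying what each was used for. Whether reads were shifted for the offset of the transposase, how duplicates were treated, and the rules by which regions were called and merged were not given in the sources used here.

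Each library came as a list of the same 84476 regions with 1 value per region, in RPKM, the read number scaled to the length of the region and to the total reads of the library, per the file headers. The authors deposited these RPKM values with no further normalization between libraries. In every library, 100% of the values times the region's length were whole multiples of 1 step, to a tolerance of 0.001 reads, so the reads per region and the total behind the RPKM could be worked out. The totals were 29232264 and 32411598 reads for Flicr WT replicates 1 and 2, and 41809276 and 19514512 reads for Flicr KO replicates 1 and 2. The lowest value in each library is 1 read, and a region listed at 1 may have held 0. Between 78.8% and 85.5% of the read numbers are even, as when mates of a pair are counted separately, so reads are not independent molecules and floors and intervals cover counting error only. An RPKM scaled to all library reads rises in every region when a larger share of the reads falls in regions, so the values were also tested after each library was centred on its median.

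The samples were grouped by the genotype in the labels, 2 Flicr KO and 2 Flicr WT. The main test was limma 3.58.1 in R 4.3.3, with the trend and robust options, on log2(RPKM + 1). Regions with a mean RPKM under the 5th percentile, 1.01, were left out, which removed 4222 regions and kept 80254. Fold changes on this scale understate the change of regions with low RPKM. P-values were adjusted by the Benjamini-Hochberg method over all regions tested, and for the chromosome X window also over the window alone, with a threshold of 0.05. Chromosomes were compared as sets with camera, with a preset correlation of 0.01 and with an estimated one. Shares of reads were compared by an exact permutation test in scipy 1.17.1. A fold against a group at the lowest value was given as a bound, with 3 reads allowed in each library of that group. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. Coordinates are of mm9 and count from 1.

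The regions named were the 10 of the window with the smallest p, the 10 with the largest fold change in each direction among called regions whose genotypes did not overlap, filled up to 5 by smallest p where fewer passed, and the 3 with the highest mean. The 5 further called regions, and the window region that voom called, were named after their values had been seen. Lists of genes for regulatory T cells and for other cell types were fixed before the data were examined, as were the tests and the alternatives unless said otherwise. The lists could not be used, because the files name no genes and no annotation of mm9 was used here. The gene table at hand is of GRCm38.p6 and served only for the order of genes around Flicr.

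The fit was tested on simulated data. Reads were drawn for the real regions from the real mean levels and the real totals of reads in regions, with 200 regions changed. The share of library reads in regions was the same in all simulated libraries, so calls that a difference in share could produce were not covered. All simulated regions also had 1 common dispersion, so regions that differ in spread were not covered. Limma's prior degrees of freedom, which measure how far it pools the spread over regions, were 20.4 and 24.0 in the simulations. In the real data they were 44.2 as deposited and 9.84 after centring, so the error and recovery rates may not carry over. Over 80253 regions tested, 45.0% of the regions changed 4-fold and 3.06% of those changed 2-fold were recovered, with 0 calls outside the changed regions, and 0 regions were called among 80252 when nothing was changed. Alternatives covered the scaling of the libraries (quantile, total, median, cyclic loess), the pseudocount, the filter, the threshold, the test, leaving out each library, and the replicate number as a block.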

Results

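Accessible chromatin was profiled by ATAC-seq in regulatory T cells of NOD mice, a strain that develops autoimmune diabetes. ATAC-seq uses a transposase that inserts sequencing adapters into open chromatin, so the number of reads in a region reflects how accessible it was. The cells carried either an intact Flicr gene (Flicr WT, 2 libraries) or a knocked-out one (Flicr KO, 2 libraries). Flicr is a long noncoding RNA gene that neighbours Foxp3, the transcription factor that defines regulatory T cells, and the series title names a modulation of Foxp3 expression and autoimmunity by it. Each library was made from 50000 CD4+ TCRβ+ cells in the upper 50% of CD25-high staining, sorted from spleen and lymph nodes of mice 8 to 10 weeks old. All 4 libraries were measured over the same 84476 regions, of which 82264 lay on autosomes and 2177 on chromosome X, with a median width of 377 bp. The labels do not say whether the replicates came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

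Depth differed between the libraries. Flicr WT replicate 1 held 29232264 reads, 7088062 of them in the regions, and Flicr WT replicate 2 held 32411598 reads with 10079117 in the regions. Flicr KO replicate 1 held 41809276 reads with 14656510 in the regions, and Flicr KO replicate 2 held 19514512 reads with 6637861 in the regions. The share of library reads that fell in the regions was 34.5% ± 0.736 (SD, n = 2) in KO and 27.7% ± 4.84 (SD, n = 2) in WT. The exact two-sided permutation test gave p = 0.333, which is the smallest p that 2 libraries against 2 allow. Flicr WT replicate 1 had the lowest share, at 24.2%, and the other WT library had 31.1%. The most accessible decile of the regions took 55.1% ± 0.0507 (SD, n = 2) of the region reads in KO and 53.5% ± 0.136 (SD, n = 2) in WT, again with an exact permutation p of 0.333. The median region had 20 reads in Flicr KO replicate 2, 22 in Flicr WT replicate 1, 32 in Flicr WT replicate 2 and 43 in Flicr KO replicate 1.

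**Figure D1:**
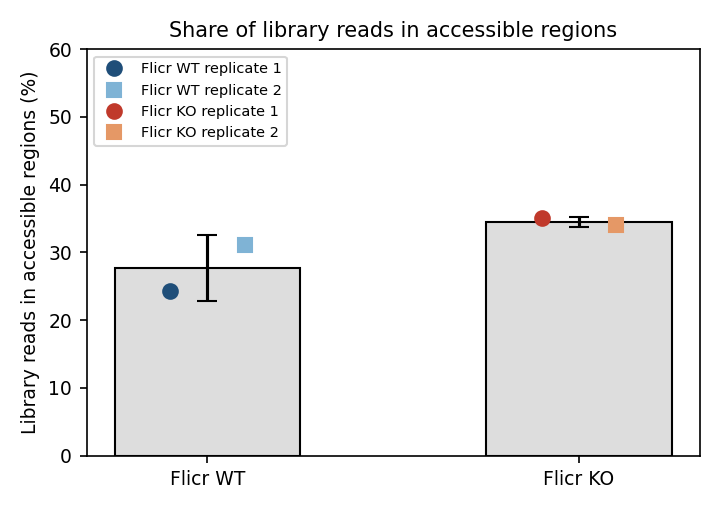
Share of library reads that fell in the 84476 accessible regions, in percent. Points are single libraries, bars are the means of 2 libraries and error bars are the SD. Both KO libraries, at 35.1% and 34.0%, lay above both WT libraries, at 24.2% and 31.1%.

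The first comparison asked whether chromatin around the targeted locus differed between the genotypes. In the mouse gene table of assembly GRCm38.p6, Flicr shares bases with both Foxp3 and Ppp1r3f, and Ccdc22 follows Foxp3. The files use the mm9 build, for which no annotation was used here, so the locus was taken as chromosome X from 7100000 to 7200000, a window recalled as holding Foxp3 and not checked against an annotation. No region could be assigned to Flicr itself or to a known Foxp3 enhancer. None of the 15 regions of the window was at or under 3 reads in both KO libraries, and where the deleted part lies was not given in the sources used here, so the window does not check the genotype labels.

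Within the window, 1 region was higher in KO. This was the 101-bp region at chromosome X, 7163777 to 7163877, with 12.6 ± 2.54 RPKM in KO and 5.0 ± 0.782 RPKM in WT (SD, n = 2 each). It rested on 45 and 28 reads in the KO libraries and on 13 and 18 reads in the WT libraries. On the log2(RPKM + 1) scale the difference was 1.17 (SE 0.27, 95% CI 0.62 to 1.72), with a limma adjusted p of 0.00129 over the window alone and 0.134 over all regions tested. With each library centred on its median, the difference was 0.95 (SE 0.21) and the limma adjusted p over the window alone was 0.00913. The call over the window was lost when Flicr KO replicate 2 was left out, where the difference was 0.98, and also with log2 CPM, with limma voom scaled to all library reads, and without limma's trend and robust options. Limma voom with read numbers scaled to the region totals called another region of the window in its place, lower in KO, at 7147763 to 7148561 (log2 fold change −1.12, adjusted p over the window 0.0369), which had 1.84 ± 0.484 RPKM in KO and 3.02 ± 0.335 RPKM in WT (SD, n = 2 each).

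The other regions of the window did not pass the test. In all, 5 of the 15 had a higher mean in KO and 10 a lower one, and 13 were lower after median centring. The median log2 fold change of the window was −0.14, and −0.36 after centring. The widest region, 7170025 to 7175112, was at 3.81 ± 0.392 RPKM in KO and 2.98 ± 0.389 RPKM in WT, a log2 fold change of 0.28 (SE 0.34). The next widest, 7148943 to 7152851, was at 4.78 ± 0.698 RPKM in KO and 4.11 ± 0.182 RPKM in WT (0.17, SE 0.31). The region at 7160858 to 7162166 was at 5.32 ± 1.76 RPKM in KO and 4.6 ± 1.34 RPKM in WT (0.17, SE 0.31). After centring, the last 2 of these had log2 fold changes of −0.04 and −0.05. The lowest fold change was at 7154313 to 7154726, with 0.410 ± 0.404 RPKM in KO and 1.71 ± 0.542 RPKM in WT (−0.96, SE 0.59, adjusted p over the window 0.641). Just beside the region that was higher, 7164599 to 7164966 was at 1.42 ± 0.0265 RPKM in KO and 2.82 ± 1.36 RPKM in WT (−0.62, SE 0.40). Regions at 7158885 to 7159220 (−0.70, SE 0.56), 7118574 to 7118824 (−0.30, SE 0.48) and 7156122 to 7157935 (−0.24, SE 0.43) were also lower in the mean, by less than their error allows to call.

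**Figure D2:**
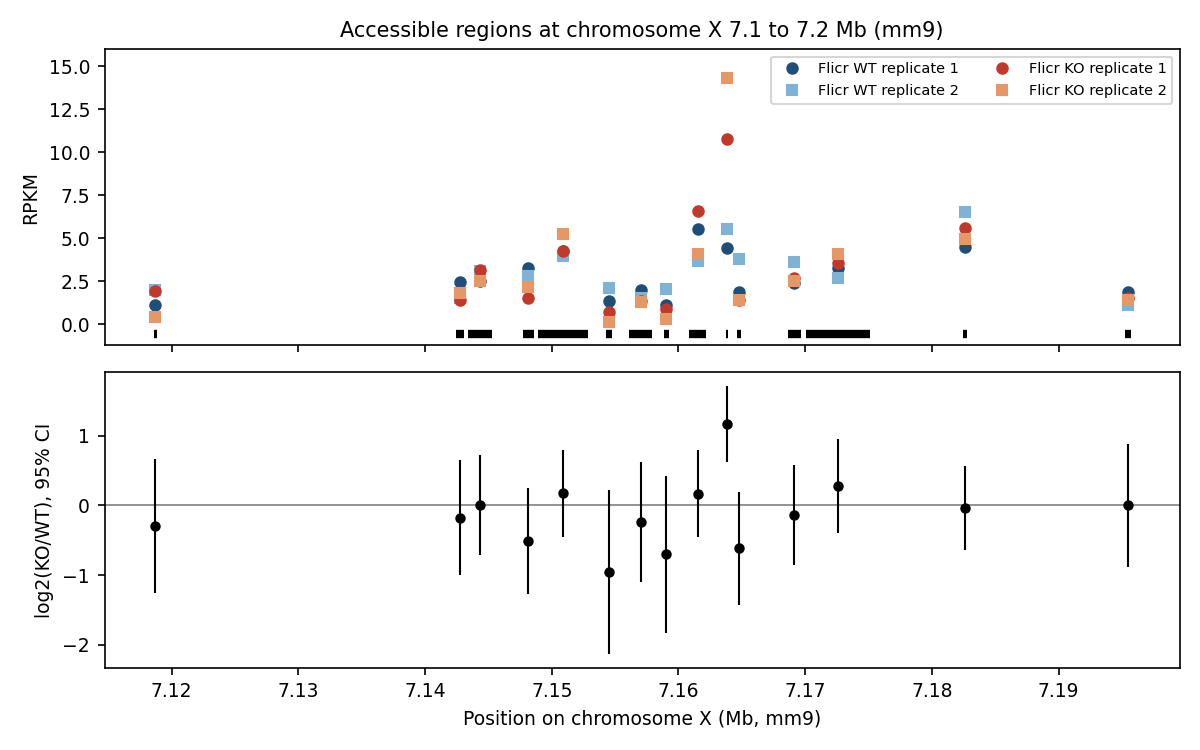
Accessible regions of chromosome X from 7100000 to 7200000 (mm9, position in Mb on the horizontal axis). The upper panel gives the RPKM of each library as a point and each region as a black bar to scale, and the lower panel gives the KO over WT log2 fold change of RPKM + 1 with its 95% CI; the interval of the region at 7163777 runs from 0.62 to 1.72.

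The second comparison asked where in the genome accessibility differed between KO and WT. Of 80254 regions tested, 15 were higher in KO and 0 were lower (limma on log2(RPKM + 1), Benjamini-Hochberg adjusted p under 0.05). At unadjusted p under 0.05 there were 6598 regions higher and 676 lower, where 4013 would be expected by chance. All regions together were shifted toward KO: the median log2 fold change was 0.21 and 71.0% of the regions were above 0. Most of this shift rested on Flicr WT replicate 1: the median was 0.07 without it and 0.35 without Flicr WT replicate 2, whose median RPKM, 2.47, was close to the 2.54 and 2.46 of the KO libraries. With each library centred on its median, limma called 0 regions in either direction, 2935 were higher and 2471 lower at unadjusted p under 0.05, and the smallest adjusted p was 0.706. Limma without its trend and robust options also called 0 regions on the values as deposited (smallest adjusted p 0.671). The median of all regions was 0.20 without Flicr KO replicate 1 and 0.24 without Flicr KO replicate 2. The count of calls also changed with the library left out. Each such fit set 1 library against 2, so its spread came from 1 genotype alone and its counts are not given.

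The 15 regions were 251 to 564 bp wide, with means from 0.130 to 7.18 RPKM in WT and from 4.58 to 22.0 RPKM in KO. Both KO libraries lay above both WT libraries in all 15. Across the tested regions both KO libraries lay above both WT libraries in 33.2%, and in 18.4% after centring, where chance gives 16.7%. The region with the smallest p, chromosome 2 at 173620559 to 173621014, was at 14.3 ± 0.841 RPKM in KO and 3.41 ± 0.703 RPKM in WT (SD, n = 2 each), a log2 fold change of 1.81 (SE 0.28, limma adjusted p 0.00328). On the log2(RPKM + 1) scale with all libraries, the largest fitted rise was on chromosome X at 10802977 to 10803289, from 0.307 ± 0.125 RPKM in WT to 6.53 ± 2.26 RPKM in KO (2.50, SE 0.39, limma adjusted p 0.00346), on 2 and 4 reads in the WT libraries and 106 and 30 in the KO libraries. A further called region lay on the same chromosome at 10800514 to 10801003, 1973 bp away, with 12.3 ± 4.82 RPKM in KO and 3.63 ± 1.20 RPKM in WT (1.5, SE 0.29). The order of the regions by fold depended on the setting, and with log2 CPM the region on chromosome 5 at 31232525 to 31232775 had the larger fold of these. In that region, both WT libraries were at the lowest value of the files, 1 read, and KO was at 4.58 ± 1.06 RPKM, at least 11.7-fold higher when 3 reads are allowed in each WT library. That bound makes no allowance for counting error in KO, and with mates counted separately 3 reads stand for fewer molecules. It does not cover the spread between samples.

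The remaining called regions spanned log2 fold changes from 1.57 to 2.12. The region at 110309747 to 110309997 of chromosome 13 was at 6.90 ± 1.06 RPKM in KO and 0.944 ± 0.987 RPKM in WT. On chromosome 8, the region at 70864508 to 70864883 was at 6.54 ± 0.411 RPKM in KO and 0.850 ± 0.427 RPKM in WT, and that at 81423845 to 81424157 was at 9.98 ± 0.636 RPKM against 2.15 ± 0.872 RPKM. On chromosome 6, the region at 38747024 to 38747274 was at 8.12 ± 0.115 RPKM in KO and 1.25 ± 0.366 RPKM in WT. Chromosome 12 held 3 called regions: 35359162 to 35359474 with 5.61 ± 0.665 RPKM in KO and 0.714 ± 0.389 RPKM in WT, 8851608 to 8851993 with 6.63 ± 1.73 RPKM and 1.10 ± 0.20 RPKM, and 35705980 to 35706543 with 22.0 ± 3.12 RPKM and 7.18 ± 3.80 RPKM. On chromosome 1, the region at 121586463 to 121586775 was at 9.09 ± 3.86 RPKM in KO and 1.59 ± 0.851 RPKM in WT. On chromosome 18, the region at 88943567 to 88943817 was at 6.55 ± 0.879 RPKM and 1.14 ± 0.835 RPKM. The last 2 lay on chromosome 16 at 35792994 to 35793490, with 8.81 ± 1.27 RPKM in KO and 2.21 ± 0.394 RPKM in WT, and on chromosome 2 at 68661478 to 68661970, with 8.51 ± 1.43 RPKM and 2.19 ± 0.440 RPKM. After median centring the 15 regions had a median log2 fold change of 1.66, against 1.87 as deposited, and all 15 were at unadjusted p under 0.05 with limma.

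**Figure D3:**
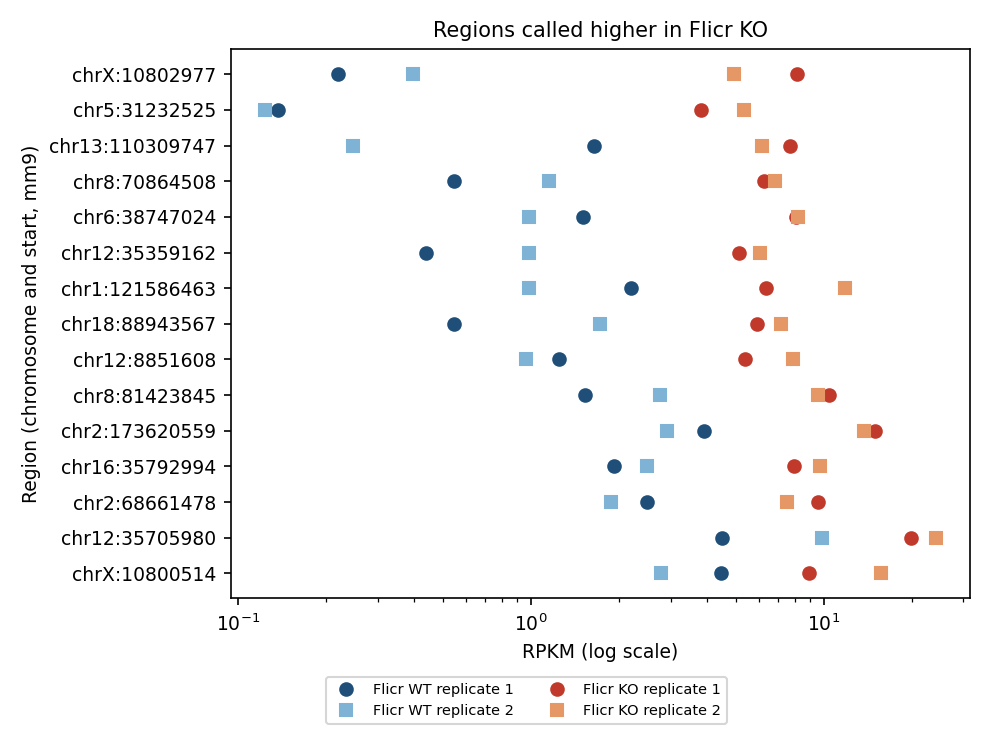
RPKM of each library (log axis) in the 15 regions called higher in KO, ordered by log2 fold change, with each region given by its chromosome and mm9 start. In every region both KO points lie to the right of both WT points; at 31232525 of chromosome 5 both WT libraries are at 1 read.

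No region was called lower in KO, and the 5 lower regions with the smallest p did not pass, with limma adjusted p from 0.220 to 0.260. Among them, the region at 140962895 to 140963145 of chromosome 4 was at 0.390 ± 0.261 RPKM in KO and 3.22 ± 0.683 RPKM in WT (log2 fold change −1.61, SE 0.44). On chromosome 12, 113955411 to 113955661 was at 0.492 ± 0.116 RPKM in KO and 3.26 ± 0.421 RPKM in WT (−1.51, SE 0.43). On chromosome 6, 67345606 to 67345856 was at 1 read in both KO libraries and at 2.88 ± 0.983 RPKM in WT. When 3 reads are allowed in each KO library, this is at least 6.40-fold lower in KO. Counting error in WT is not allowed for in that bound. The region at 3000005 to 3000255 of chromosome 9 was at 1.57 ± 0.483 RPKM in KO and 5.40 ± 2.05 RPKM in WT (−1.29, SE 0.36), and that at 79510227 to 79510477 of chromosome 17 was at 2.05 ± 1.16 RPKM in KO and 5.91 ± 1.77 RPKM in WT (−1.21, SE 0.35). Limma voom on read numbers scaled to the region totals called 20 regions higher and 12 lower, and 5 of the 15 regions were among its calls. Scaled to all library reads, voom called 13 higher and 0 lower, 6 of the 15 among them. The region at 10802977 of chromosome X was not among them (limma voom adjusted p 0.297). Over the alternatives that kept all libraries, its limma adjusted p ranged from 6.96e-05 to 0.866.

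The most accessible regions showed the general shift. The region of highest mean, chromosome 16 at 42874852 to 42877090, was at 132 ± 6.10 RPKM in KO and 104 ± 13.3 RPKM in WT (log2 fold change 0.35, SE 0.20). Those at 9534982 to 9535757 of chromosome 1 and 95067607 to 95068486 of chromosome 6 each had a log2 fold change of 0.49 (SE 0.20). None of the 3 passed, with limma adjusted p from 0.493 to 0.603, and after median centring their log2 fold changes were 0.13, 0.27 and 0.27. With cyclic loess the region on chromosome 16 was at −0.11. On the log2(RPKM + 1) scale the shift grew with the level of a region. That scale understates the change of regions with low RPKM, so the pseudocount may add to the rise. The rise was not computed with another pseudocount. The median log2 fold change was 0.02 in the decile of regions with the lowest mean RPKM and 0.35 in the highest decile, and after median centring it ran from −0.20 to 0.13.

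**Figure D4:**
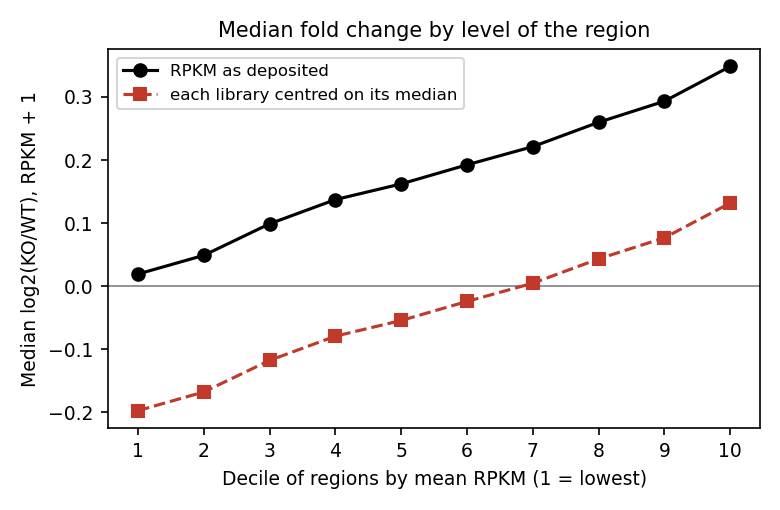
Median KO over WT log2 fold change of RPKM + 1 in deciles of the 80254 tested regions by mean RPKM, numbered from the lowest. The values as deposited lie above 0 in every decile and reach 0.35 in the highest one; after each library is centred on its median the line runs from −0.20 to 0.13.

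The third comparison asked whether chromosome X, which carries the targeted gene, moved apart from the autosomes. It did not pass the test. The 2083 tested regions of chromosome X had a median log2 fold change of 0.25 and the other regions 0.21, a difference of 0.04 (camera p = 0.412 with a preset correlation of 0.01, and p = 0.845 with an estimated correlation). Chromosome X held 2 of the 15 called regions. The adjusted camera p was 0.99989 for each chromosome tested as its own set.

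Whether replicates resembled each other more than libraries of different genotype did depended on the measure. By correlation the KO replicates did and the WT replicates did not. Across regions, which are not independent replicates, Pearson's correlation of log2(RPKM + 1) was 0.859 between the KO libraries and 0.844 between the WT libraries, and 0.839 to 0.850 between a KO and a WT library. The mean within genotypes exceeded that between genotypes by 0.0063. Spearman's correlation was 0.774 between the KO libraries, 0.745 between the WT libraries and 0.747 to 0.753 across genotypes. The median absolute log2 difference after median centring was 0.319 between the KO libraries, 0.323 between the WT libraries and 0.312 to 0.354 across genotypes, so that 1 pair of different genotype was the closest. With a pseudocount of 5 the WT libraries were the closest pair, at 0.152, against 0.153 for the KO libraries and 0.156 to 0.178 across genotypes.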

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

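Limma voom on the recovered reads, thinning to equal region reads, and centring without limma's trend and robust options were chosen after seeing the data. Against 15 regions higher and 0 lower in KO, 0 were higher with quantile normalization, total scaling, median centring, cyclic loess, thinned reads, no trend, and centring without trend. There were 23 higher with log2 CPM (13 of the 15 among them), 25 without a filter (15), 10 with a filter at the 25th percentile (10), 13 with voom scaled to all library reads (6), 20 higher and 12 lower with voom scaled to region totals (5), 30 at adjusted p under 0.10, and 6598 higher and 676 lower at unadjusted p under 0.05. Leaving out a library gave 0 to 6440 higher and 0 to 18 lower. The median log2 fold change of all regions, 0.21, became −0.0044 (quantile), −0.023 (total), −0.0050 (median, with or without trend), −0.0059 (loess), −0.039 (voom, region totals) and −0.033 (thinned), as those scalings remove a common shift by construction, 0.10 with a pseudocount of 5, and 0.069 (without Flicr WT replicate 1) to 0.35 (without Flicr WT replicate 2) when a library was left out. The window's count of 1 fell to 0 with log2 CPM, no trend, voom scaled to all library reads and centring without trend. Its call was also lost without Flicr KO replicate 2, which left 1 KO library. The cause was not tested, except for the common shift and for the calls lost on median centring, which are weighed among the other observations. The fold change of the region at 7163777 of chromosome X ranged from 0.81 to 1.36. Chromosome X against the other regions stayed above 0 and short of the threshold in all 20 settings (0.01 to 0.06, camera p 0.269 to 0.845). With median centring, without trend, with a replicate block and with an estimated correlation the difference was fixed at its main value, 0.039, so those settings do not test its sign. The 15 regions kept their sign in all 20 refits (13 tested without chromosome X). Leaving out a library could not change it, as both KO libraries lay above both WT libraries in all 15. Their median fold change, 1.87, was 0.98 with a pseudocount of 5 and 2.49 with log2 CPM. Of 645 fold changes of named regions, 456 kept their direction and side of the threshold, 166 lost the call, 5 gained one and 18 changed sign, none of them called. Those were the window regions at 7148943 and 7160858 with quantile normalization (−0.078 and −0.10), total scaling (−0.089 and −0.10), median centring with or without trend (−0.044 and −0.050), loess (−0.081 and −0.096) and thinned reads (−0.084 and −0.12), the region at 7148943 with voom scaled to region totals (−0.14), and the region of highest mean at 42874852 with quantile normalization (−0.045) and loess (−0.11). When a library was left out, the region at 7160858 ranged from −0.12 to 0.45 and that at 7118574 from −0.82 to 0.22. With the replicate number as a block, 42 regions were higher, 0 lower and 1 called in the window; same-numbered libraries shared no deviation (correlation 0.0031, 2 pairs), so the numbers were not taken to pair them. Planned tests for count tables, peak overlaps and gene lists were not run, since the values are RPKM over shared regions with no gene names. At these depths with 2 libraries per group, 3.06% of simulated 2-fold changes were recovered, in a simulation with 1 dispersion for all regions. Depth, number of libraries and pseudocount were not told apart.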

Other observations

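Except for the test on neighbouring regions after cyclic loess, the tests below were chosen after the results they bear on had been seen.

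The called regions at 10800514 and 10802977 of chromosome X lie 3.60 Mb from the Foxp3 window, and the 4 other regions within 50 kb of them all had a higher mean in KO, with a median log2 fold change of 0.35 after median centring. A hypothesis is that a stretch of chromosome X around the targeted gene differs between the genotypes, as a segment carried along from the strain or cell line of the knockout might. Within 5 Mb of the window, 11.9% of 159 regions were at unadjusted p under 0.05 after centring (13 higher and 6 lower in KO), against 6.65% elsewhere on the chromosome. With the pair, that share lies at percentile 96.8 of shifts of the p-values along the chromosome, but without the pair it is 10.8%, at percentile 93.9. The median of the 4 neighbours lies at percentile 94.1 of stretches of 4 regions, too few to decide. Among 243 stretches of 10 Mb across the genome with at least 100 regions, the median share was 6.72%, the highest 16.5%, and 4 were as high as the stretch with the pair. In the other 2 ways of splitting the libraries the share was 2.52% and 4.40%. Over all tested regions these splits also had fewer at unadjusted p under 0.05 with limma after centring, 3340 and 3369 against 5406. The hypothesis stays open, and sequence variants in the reads, not analysed here, would test it.

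The 15 regions higher in KO with 0 lower came with a larger share of reads in regions in both KO libraries. At unadjusted p under 0.05, 90.7% of the regions were higher in KO as deposited, and 47.7% once the libraries were scaled to the total of all regions; that scaling removes a common shift by construction, so it does not tell whether preparation or genotype raised the share. A common shift does not account for the size of the 15 fold changes. After median centring the lowest of them was 1.28, against a median of 0.21 for all regions as deposited. The 15 were selected for large differences in these same libraries, and their calls depended on the test both with the shift and without it. On the values as deposited, limma without its trend and robust options called 0 of the 15 (smallest adjusted p 0.671). With region totals, limma called 0 of the 15 (smallest adjusted p 0.724). Limma voom with that scaling called 5, where the median of all regions was −0.039. Over all regions its smallest adjusted p was 2.7e-74, from 2 libraries against 2, while limma voom scaled to all library reads gave 6.2e-04. The reason for so small a value was not examined, which limits what these 5 calls show. Whether the shift produced the calls stays open, as centring removed the shift and weakened limma's pooling together. The calls of all 15 ended on centring, together with a weaker pooling of the spread by limma, whose prior degrees of freedom fell from 44.2 to 9.84. The median t of the 15 changed little, to 5.49 after centring, 0.972 of the 5.65 before. The calls thus ended with the weaker pooling and not with a smaller t, and their adjusted p as deposited rests on that pooling. Their median log2 fold change was 1.66 (SE 0.31) after it and 1.87 (SE 0.34) before. With 3 splits of 4 libraries into 2 and 2 a share under 0.05 cannot be reached; the real split called 15 regions and the highest of the others 1.

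The region at 7163777 of chromosome X, higher in KO, is 101 bp wide and holds few reads. A common shift does not account for it alone: after median centring its log2 fold change was 0.95 (SE 0.21), with an adjusted p over the window of 0.00913. Without limma's trend and robust options the call was lost both as deposited (1.17, adjusted p 0.0891) and centred (0.95, adjusted p 0.0878), so that loss came from the test and not from the scaling. Pooled read pairs, 36 in KO and 15 in WT, gave a ratio of 1.93 per read in regions, with an exact 95% interval of 1.03 to 3.80, and of 0.783 to 5.37 when widened for the choice among 15 regions, so counting error is not excluded, and limma voom gave the region an unadjusted p of 0.115 with region totals and 0.0386 with all library reads. A difference of the locus in the knockout stays open, and was not tested.

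Differences between KO and WT were small but shared by neighbouring regions more than in the other splits of the libraries at most distances. With 3 splits in all, the real one coming first cannot reach a share under 0.05. After median centring, the fold changes of regions 1000 to 5000 bp apart had a correlation of 0.0603 (SE 0.0066), across region pairs, which are not independent. In the other splits it was 0.0213 and 0.0194. At 5000 to 20000 bp it was 0.0481, against 0.0107 and 0.0362. At 0 to 1000 bp it was 0.0586 (SE 0.0081), against 0.0362 and 0.0301. A dependence of the fold change on the level of a region might produce this, but after cyclic loess, which removes such a trend, the correlation at 1000 to 5000 bp was 0.0587, against 0.0207 in the highest of the other splits, though at 5000 to 20000 bp it was 0.0405 (SE 0.0065), against 0.0336. It was again higher at 20000 to 100000 bp, with 0.0359 against 0.0074, and at 0 to 1000 bp, with 0.0777 against 0.0336. Regions at unadjusted p under 0.05 numbered 5406 after centring, against 3340 and 3369 in the other splits, and 4689 after loess, against 3575 and 3646, so part of that excess went with the level of a region. A genotype effect spread over many weak sites is a hypothesis that these values leave open, as is an unrecorded difference in preparation.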
